A study of Homo sapiens with 24 samples.

How the data were processed

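Messenger RNA levels were measured with single-colour Agilent microarrays in 4 human neuroblastoma cell lines, SK-N-BE, SK-N-SH, NGP and IMR32. Each line had been given 0.1% DMSO, the solvent control, or EPZ-6438 (tazemetostat, an inhibitor of the histone methyltransferase EZH2) at 1 µM. RNA was taken on day 3 in SK-N-BE, SK-N-SH and NGP and on day 4 in IMR32. The 8 groups held 3 arrays each, and each of the 24 arrays carried 1 sample. Groups were taken from the sample labels.

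The deposited values were signal intensity, background-subtracted and detrended within each array by the authors with Agilent Feature Extraction 11.5.1.1, per the file headers, with no normalization between arrays. The series table held the same intensity values for each of its 24 columns, identical in 100% of them on every array. The 75th percentile of the processed signal ran from 126 to 246 over the arrays, between 49.6% and 55.2% of the spots were well above background, and no spot was saturated. The scanner software marked 3 arrays for evaluation. The number of arrays limits the precision.

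Control spots and spots marked as outliers were left out, and the spots of a probe were averaged. Each array's log2 intensity had that array's 75th percentile subtracted. Probes were named through their RefSeq accessions. Of 50599 probes, 30275 matched 1 current symbol, 0 matched several and 20324 matched none, and the last kept the name in the deposited files and were left out of the gene tests. The array annotation was on an older genome build than the RefSeq table, and no genome came with the data, so no positions are given. The 21743 genes include 6289 with more than 1 probe. A gene is represented by its probe with the highest mean signal over the 24 arrays. Among called genes with a further measured probe, all probes had the same direction in 84.9% in SK-N-BE, 89.9% in SK-N-SH, 83.6% in NGP and 86.7% in IMR32. EED, a core subunit of the same complex as EZH2, had no matched probe and was not analysed here.

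A gene was tested in a line where its probe was well above background on at least 3 of the line's 6 arrays, with the share of its spots at 0.5 or more. A linear model with 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual and 1.84 prior degrees of freedom), and tables were read with the data.table package (version 1.17.8). Contrasts gave EPZ-6438 minus DMSO in each line, the mean over the lines, the difference between each pair of lines, an F test of any difference of response between the lines, and an F test of the DMSO groups. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and are two-sided. "Rose" and "fell" are used of genes and lists past that threshold. Changes are log2 EPZ-6438 minus DMSO, with standard errors from the model and n = 3 arrays per group. Where no array of a group was well above background, a fold is given only as a bound, "at least N-fold". It was computed from the bright group's mean over all replicates against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

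The numbers 1 to 3 in the labels were checked for pairing. All 3 slides held a single replicate number of all 8 groups. Over the 12 pairs of arrays compared, the deviations of same-numbered arrays from their group means correlated between 0.148 and 0.433. Each was over 0.1 and above the correlation with other numbers, so the numbers were treated as pairs. Same-numbered arrays also shared a slide, so this check cannot tell paired samples from a difference between slides. The comparisons are given without the block, as designed, and a blocked value is given for a result whose call it moved. Counts with the replicate block are given per line, for the mean of the lines, over all pairs and for genes called in more than 1 line. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples.

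Gene lists were tested with camera from limma, which asks whether a list's genes moved relative to the other genes. A preset correlation of 0.01 between genes was used, an estimated correlation served as an alternative, and lists with fewer than 5 tested genes were left out. The 31 lists were Polycomb repressive complex (PRC2) subunits, genes reported as repressed by EZH2, HOX genes, developmental transcription factors, neuronal maturation, adrenergic identity, mesenchymal identity, Schwann cell and neural crest markers, epithelial markers, blood and endothelial cell markers, MYC targets, DNA replication and G1/S genes, mitosis genes, interferon response, antigen presentation, p53 targets, integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, hypoxia and glycolysis, immediate early genes, BMP and TGF-beta signalling, Wnt signalling, Notch signalling, imprinted genes, cancer-testis genes, clustered protocadherins, DNA methylation enzymes, other chromatin regulators, potassium and calcium channels, and cytosolic ribosomal proteins. Sharing of called genes between lines was tested with a one-sided Fisher's exact test over the genes tested in both lines.

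The lists, the tests and the rule for named genes were fixed before the data were examined. That rule named EZH2, EZH1, EED, SUZ12, CASZ1, CLU, RUNX3, NGFR, MYCN and CDKN1A in any case, and some further genes that are not reported here. It added, per line, the 8 largest rises and 8 largest falls among called genes whose EPZ-6438 arrays all lay on the same side of the DMSO arrays. It also named the genes called the same way in all 4 lines, up to 10 per direction by mean change, and the 8 genes with the smallest p for a difference between lines. Per list and line, up to 4 called members with the largest change could be named, or 2 as values where none was called. Named falls and list members whose call ended when 1 array was left out are mostly given as counts.

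The procedure was tested on simulated data with the spread of these arrays. A change of 0.5 on the log2 scale was recovered in 64.2% to 70.1% of the changed genes, a change of 1 in 86.6% to 91%, and a change of 2 in 95.5% to 100%, depending on the line. Between 2.37% and 4.57% of the simulated calls were false. A list shifted by -0.3 in NGP was found, and 0 of the other lists were called. The simulated noise was drawn independently for each gene and array, without correlation between genes and without a difference between slides. The simulation therefore cannot show how often lists of correlated genes are called falsely, nor the share of false calls where slides differ.

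Alternatives were the array median or quantile normalization in place of the 75th percentile, normexp background correction with an offset of 50 followed by quantile normalization, the series table, no filter on dim probes or a filter on all 6 arrays, the mean of a gene's probes, each line fitted alone, eBayes with trend and robust options, the replicate number or the slide as a block, array weights, at least 2-fold, an adjusted p under 0.01, and each array left out in turn. Normexp used the median spot signal because the files held no mean signal. The series table moved no value, being identical. Scan date was not used as a block because all arrays shared a single date. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.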

Results

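Gene expression was measured in 4 human neuroblastoma cell lines, cultured cells derived from a childhood tumour of the sympathetic nervous system. EPZ-6438, also called tazemetostat, blocks EZH2, the enzyme of Polycomb repressive complex 2 (PRC2) that places a repressive methyl mark on histone H3. Each line was compared with its own control in DMSO, the solvent of the drug. The 8 groups had 3 arrays each, with samples taken on day 3 in SK-N-BE, SK-N-SH and NGP and on day 4 in IMR32. Between 49.6% and 55.2% of the spots of an array were well above background. The series concerns resistance of neuroblastoma to EZH2 inhibitors. The labels do not say which lines were sensitive or resistant.

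Large changes after EPZ-6438 were mostly rises in every line. Genes that rose at least 2-fold numbered 390 in SK-N-BE, 419 in SK-N-SH, 207 in NGP and 320 in IMR32, and those that fell at least 2-fold numbered 6, 6, 4 and 9. With genes not measurable in a group counted at their bound, the rises numbered 379, 349, 185 and 280 and the falls 5, 3, 3 and 8. At an adjusted p under 0.05 of any size (limma), 1882 genes rose and 1642 fell in SK-N-BE of 14588 tested. In SK-N-SH 1162 rose and 900 fell of 14678, in NGP 874 rose and 454 fell of 13948, and in IMR32 937 rose and 514 fell of 14475. An unadjusted p under 0.05 was reached by 5071, 3480, 2939 and 3177 genes in these lines. The treated arrays did not overlap the control arrays for 39.07%, 31.84%, 26.38% and 30.72% of the tested genes in these lines, where chance gives 10%.

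Scaling each array to its median in place of its 75th percentile moved the median change of the genes tested in all lines from -0.02 to -0.18 in SK-N-BE, from -0.02 to -0.16 in SK-N-SH, from -0.03 to -0.10 in NGP and from -0.05 to -0.18 in IMR32. Falls then outnumbered rises in SK-N-BE (742 up, 1898 down) and SK-N-SH (601 up, 1077 down), and the counts were 404 up and 137 down in NGP and 437 up and 396 down in IMR32. Directions of gene lists are therefore given relative to the other genes. The median signal of an array ran from 8.417 to 15.916, close to the lowest signal well above background (6.7406 to 8.8979 over the arrays). Median scaling thus rests on spots near background. With quantile normalization the median changes were -0.032 in SK-N-BE, -0.015 in SK-N-SH, -0.014 in NGP and -0.027 in IMR32. After normexp with its added offset, which shrinks the changes of dim genes, 55, 41, 27 and 40 genes rose at least 2-fold. With the replicate number as a block, 5115 genes were called in SK-N-BE, 2976 in SK-N-SH, 2268 in NGP and 2641 in IMR32. With the slide as a block the counts were 5142 in SK-N-BE, 3037 in SK-N-SH, 2439 in NGP and 2704 in IMR32.

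**Figure D1:**
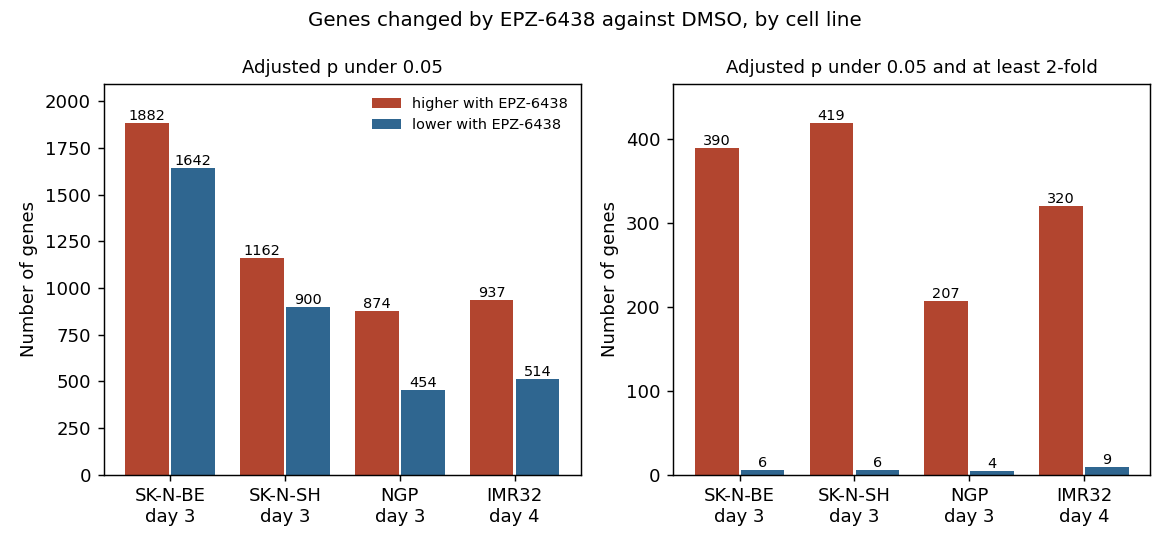
Number of genes higher and lower after EPZ-6438 in each cell line (n = 3 arrays per group), at an adjusted p under 0.05 on one panel and with at least 2-fold change on the other. Rises of at least 2-fold number 390, 419, 207 and 320 against 6, 6, 4 and 9 falls; with median scaling, falls of any size outnumber rises in SK-N-BE and SK-N-SH.

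The first question was whether the drug's target complex and genes reported as repressed by EZH2 changed. EZH2 itself fell by 0.50 ± 0.06 (SE, log2, n = 3 against 3) in SK-N-SH (adjusted p = 1.16e-05) and by 0.30 ± 0.06 in NGP (adjusted p = 0.00441). It gave -0.16 in SK-N-BE (adjusted p = 0.0856, 0.0329 with the replicate block and 0.0469 without DMSO array 3) and -0.06 in IMR32 (adjusted p = 0.641). SUZ12, a core PRC2 subunit, fell in SK-N-BE by 0.20 ± 0.04 and in SK-N-SH by 0.21 ± 0.04, and its values were -0.13 in NGP (adjusted p = 0.068, 0.0305 with the replicate block and 0.0447 without EPZ-6438 array 1) and -0.14 in IMR32. The IMR32 call (adjusted p = 0.0412) ended when any 1 of the 6 arrays was left out, with adjusted p from 0.0559 to 0.164. EZH1, the paralogue of EZH2, had log2 differences of -0.05, 0.12, -0.19 and -0.09 in SK-N-BE, SK-N-SH, NGP and IMR32, with no call. PRC2 subunits fell relative to other genes in SK-N-SH, with 0 of 10 up and 3 down, 0 and 4 adjusted over the list alone (median -0.13, adjusted p = 0.00421). They had 0 up and 4, 1 and 1 down in SK-N-BE, NGP and IMR32, without a call of the list (adjusted p = 0.0809, 0.0663 and 0.0714). The replicate block gave 0.0286 in NGP and 0.0299 in IMR32, and the slide block gave 0.0333 in SK-N-BE. Genes reported as EZH2-repressed rose in the other lines, as given for each, but in IMR32 they had 2 of 14 up and 1 down, 3 and 1 adjusted over the list alone, with no call (median 0.06, adjusted p = 0.218, and 0.0111 with no filter on dim probes). Their medians in IMR32 were 0.038, -0.024 and 0.259 on the 3 slides. The EZH2 call in NGP ended with median scaling (adjusted p = 0.0807), with the line fitted alone (0.0885) and without slide 1 (0.0579). The SUZ12 calls in SK-N-BE and SK-N-SH ended with each line fitted alone (0.0761 and 0.0557).

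NGFR, a neurotrophin receptor, was at least 3.26-fold higher in SK-N-BE (adjusted p = 1.53e-07), where no DMSO array measured it. It rose by 1.86 ± 0.18 in SK-N-SH (adjusted p = 3.63e-07) and by 1.33 ± 0.18 in IMR32 (adjusted p = 3.37e-05), and its difference was 0.13 in NGP (adjusted p = 0.773). RUNX3, a transcription factor, rose by 1.26 ± 0.28 in SK-N-BE (adjusted p = 0.00279) and by 1.19 ± 0.28 in NGP (adjusted p = 0.00977), calls that ended without slide 1 (0.0795 and 0.146). Its difference of 0.97 in SK-N-SH (adjusted p = 0.0254) lost its call without any 1 of the 6 arrays, with adjusted p from 0.0566 to 0.074. In IMR32 RUNX3 was at least 1.34-fold higher, measured on 2 of 3 EPZ-6438 arrays, and was left untested by the filter. With no filter on dim probes it was called there (limma, adjusted p = 0.000389). The zinc finger factor CASZ1 rose by 1.17 ± 0.13 in SK-N-SH on its brightest probe (adjusted p = 1.7e-06), while its other probe gave -0.12. In the other lines CASZ1 gave -0.06, -0.01 and 0.08 in SK-N-BE, NGP and IMR32. CLU, the secreted chaperone clusterin, rose by 0.51 ± 0.09 in IMR32 (adjusted p = 0.000456), a call that ended with median scaling (0.147) and with normexp (0.0694). CLU gave 0.16, -0.01 and 0.17 in SK-N-BE, SK-N-SH and NGP, and the replicate block brought adjusted p to 0.0195 in SK-N-BE and 0.0297 in NGP.

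MYCN, the oncogene amplified in many neuroblastomas, was 0.26 higher in SK-N-BE (adjusted p = 0.0149), a call that ended without DMSO array 3 (adjusted p = 0.0817) or EPZ-6438 array 2 (0.0542) with median scaling (0.525), with the line fitted alone (0.0695) and without slide 1 (0.127). MYCN gave -0.14 in IMR32 (adjusted p = 0.286) and -0.22 in NGP (adjusted p = 0.0646, and 0.048 with the slide block), and was not above background in SK-N-SH. CDKN1A, an inhibitor of cyclin-dependent kinases, gave 0.26, 0.14 and 0.30 in SK-N-SH, NGP and IMR32 with no call.

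In SK-N-BE, genes of DNA replication and mitosis fell, and genes of Wnt signalling and genes reported as EZH2-repressed rose. The largest rises included SELENOP, a plasma selenium carrier (at least 6.88-fold higher, adjusted p = 1.56e-15), the chemokine CXCL14 (at least 11-fold) and F11R, a tight junction protein (at least 4.03-fold). CD70, a ligand of the tumour necrosis factor family, rose by 4.65 ± 0.43 (adjusted p = 1.69e-07), with 1 of 3 DMSO arrays measuring it. FAM43B was at least 5.48-fold, SCGB1D1 at least 3.32-fold and HOXC13 at least 3.68-fold higher, and the chloride transporter gene CLCN4 rose by 4.19 ± 0.59, measured on 1 of 3 DMSO arrays. The largest falls included the small nucleolar RNA SNORA30 (-1.23 ± 0.16), the quinone reductase NQO1 (-1.10 ± 0.25), the histone gene H3C15 (-0.97 ± 0.11) and the secretory chaperone SCG5 (-1.13 ± 0.29, measured on 2 of 3 EPZ-6438 arrays). Of the 8 largest falls, 3 lost their call without 1 array and are not named.

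Of 44 DNA replication and G1/S genes, 1 rose and 40 fell in SK-N-BE, 1 and 42 adjusted over the list alone (median -0.46, adjusted p = 4.78e-24). Examples were the replication fork gene GINS4 (-0.84 ± 0.07) and the cell cycle factor E2F1 (-0.66 ± 0.06). Of 44 mitosis genes 0 rose and 40 fell, 0 and 41 adjusted over the list alone (median -0.56, adjusted p = 7.51e-30), among them the kinase gene AURKB (-0.76 ± 0.08) and the topoisomerase gene TOP2A (-0.69 ± 0.05). Genes reported as EZH2-repressed rose, with 8 of 13 up and 0 down, 9 and 0 adjusted over the list alone (median 0.64, adjusted p = 3.77e-07). They included TIMP3, a metalloproteinase inhibitor (at least 4.47-fold higher), the cell cycle inhibitor CDKN1C (1.70 ± 0.14) and the ubiquitin ligase gene FBXO32 (1.37 ± 0.09). Wnt signalling genes rose, with 14 of 21 up and 0 down by both counts, the second adjusted over the list alone (median 0.35, adjusted p = 5.11e-07). NKD2, a Wnt inhibitor, rose by 2.49 ± 0.11, the receptor gene FZD1 by 1.11 ± 0.09 and the ligand gene WNT11 by 1.25 ± 0.20. BMP and TGF-beta signalling rose, with 9 of 22 up and 0 down, 12 and 0 adjusted over the list alone (median 0.26, adjusted p = 2.24e-05). Its ligand gene BMP6 was at least 3.25-fold higher and the receptor gene TGFBR1 rose by 0.82 ± 0.09.

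Imprinted genes, which are expressed from a single parental copy, rose in SK-N-BE with 8 of 19 up and 0 down, by both counts, the second adjusted over the list alone (median 0.35, adjusted p = 0.000138). Among them the growth factor gene IGF2 rose by 2.54 ± 0.19, DLK1, a Notch-like ligand, by 1.89 ± 0.24, and the adaptor gene GRB10 was at least 3.26-fold higher. Antigen presentation rose, with 9 of 29 up and 0 down, 11 and 0 adjusted over the list alone (median 0.32, adjusted p = 0.000151). HLA-DQA1 and HLA-G, of MHC classes II and I, rose by 1.21 ± 0.09 and 0.50 ± 0.05. Potassium and calcium channels rose, with 10 of 30 up and 0 down, 11 and 0 adjusted over the list alone (adjusted p = 0.000151), including KCNMA1 (1.32 ± 0.09) and CACNA1A (1.44 ± 0.20). Developmental transcription factors had 18 of 66 up and 3 down, 22 and 3 adjusted over the list alone (adjusted p = 0.000704), a list whose median was below 0 with median scaling. POU4F1, a factor of sensory neurons, rose by 1.96 ± 0.26, and LHX6 was at least 3.45-fold higher. Ribosomal protein genes had 7 of 57 up and 0 down, 3 and 0 adjusted over the list alone (adjusted p = 0.000834), but adjusted p = 0.639 with an estimated correlation and a median below 0 with median scaling (0.0606). The ribosomal call also ended without EPZ-6438 array 1 (0.0727), with quantile normalization (0.229) and with normexp (0.131). Endoplasmic reticulum chaperones had 4 of 17 up and 0 down by both counts, the second adjusted over the list alone (adjusted p = 0.0435), but adjusted p = 0.289 with an estimated correlation. Without DMSO array 3 or EPZ-6438 array 1 their adjusted p was 0.0777 or 0.136, and their median was below 0 with median scaling (0.184).

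SK-N-SH shared the fall of replication and mitosis genes and had the largest single rises. CD24, a surface glycoprotein, was at least 53.8-fold higher (adjusted p = 1.72e-16), CD70 rose by 6.35 ± 0.43, and ARHGDIB, an inhibitor of small GTPases, rose by 4.82 ± 0.09 with 2 of 3 DMSO arrays measuring it. The neuropeptide-processing enzyme gene CPE was at least 5.71-fold, TIMP3 at least 6.01-fold, RFPL4AL1 at least 13.3-fold, the leukocyte tetraspanin gene CD53 at least 5.72-fold and the endocytic adaptor gene DAB2 at least 5.70-fold higher. Among the falls were the centriole genes HYLS1 (-1.24 ± 0.15) and PLK4 (-0.89 ± 0.12), ZNF114 (-0.92 ± 0.18) and the receptor gene P2RY8 (-1.14 ± 0.17, measured on 1 of 3 EPZ-6438 arrays). Of the 8 largest falls, 2 lost their call without 1 array and are not named.

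In SK-N-SH 0 DNA replication and G1/S genes rose and 42 of 44 fell, 0 and 43 adjusted over the list alone (median -0.48, adjusted p = 3.99e-37), such as DTL (-0.71 ± 0.08), which targets replication factors for degradation, and the polymerase gene POLE2 (-0.77 ± 0.09). Of 44 mitosis genes 0 rose and 42 fell, 0 and 43 adjusted over the list alone (median -0.40, adjusted p = 3.42e-31), such as the motor gene KIF11 (-0.61 ± 0.07) and the checkpoint kinase gene TTK (-0.58 ± 0.08). Genes reported as EZH2-repressed rose with 9 of 14 up and 0 down, by both counts, the second adjusted over the list alone (median 0.91, and 0.87 with bounds, adjusted p = 3.04e-10). CDKN2A, a tumour suppressor of the cell cycle, rose by 1.76 ± 0.09, and the cell cycle inhibitor CDKN1C by 1.57 ± 0.14. HOX genes, which set position along the body axis, rose with 7 of 14 up and 0 down, 9 and 0 adjusted over the list alone (adjusted p = 1.13e-07). HOXD10 rose by 1.04 ± 0.08, and HOXD13, HOXB6 and HOXB13 were at least 4.50-fold, 4.44-fold and 2.75-fold higher. Neuronal maturation genes rose with 14 of 28 up and 1 down, 15 and 2 adjusted over the list alone (adjusted p = 1.13e-07). L1CAM, an adhesion molecule of axons, was at least 3.83-fold higher and the neurotrophic receptor gene GFRA2 rose by 1.33 ± 0.06.

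Interferon response genes rose in SK-N-SH, with 14 of 38 up and 0 down, 16 and 0 adjusted over the list alone (median 0.22, adjusted p = 3.1e-06). MX2, an antiviral GTPase, was at least 4.86-fold higher, and OAS2, a sensor of double-stranded RNA, rose by 2.45 ± 0.60 with 2 of 3 DMSO arrays measuring it. Antigen presentation had 6 of 28 up and 0 down by both counts, the second adjusted over the list alone (adjusted p = 0.00421), with HLA-DMB at least 4.22-fold higher and HLA-DPA1 up by 1.54 ± 0.27. Wnt signalling had 7 of 25 up and 0 down, 9 and 0 adjusted over the list alone (adjusted p = 7.17e-05), including the secreted inhibitor SFRP1 (1.59 ± 0.05) and WNT6 (1.44 ± 0.14). Notch signalling had 7 of 20 up and 1 down, 8 and 1 adjusted over the list alone (adjusted p = 9.4e-05), with its target HES4 up by 1.14 ± 0.06. Cancer-testis genes, normally restricted to the germline, had 3 of 17 up and 0 down by both counts, the second adjusted over the list alone (adjusted p = 0.00432), and SPANXB1 rose by 4.24 ± 0.14. Developmental transcription factors had 14 of 52 up and 1 down by both counts (adjusted p = 9.04e-06), with a median below 0 under median scaling. NKX3-2, a homeobox factor of the skeleton, was at least 4.82-fold higher. BMP and TGF-beta signalling had 6 of 28 up and 0 down, 8 and 0 adjusted over the list alone (adjusted p = 0.00241), with a median below 0 under median scaling. The BMP antagonist NOG was at least 3.735-fold higher and INHBA, an activin subunit, rose by 1.54 ± 0.19. Channels had 7 of 20 up and 0 down by both counts (adjusted p = 0.000364), including KCNN1 at least 2.40-fold higher, with a median below 0 under median scaling. Immediate early genes had 5 of 23 up and 0 down, 7 and 1 adjusted over the list alone (adjusted p = 0.0111, and 0.0535 with the mean of each gene's probes), with a median below 0 under median scaling. Imprinted genes had 5 of 20 up and 0 down by both counts (adjusted p = 0.0197), including IGF2 at least 3.08-fold higher, with a median below 0 under median scaling. That call ended with the replicate block (0.0656), without DMSO array 1 (0.0842), with normexp (0.0574), with the filter on all 6 arrays (0.0699) and without slide 1 (0.202).

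Further list calls in SK-N-SH did not hold with an estimated correlation. Cholesterol synthesis had 10 of 27 up and 0 down, 13 and 0 adjusted over the list alone (adjusted p = 6.49e-05), and adjusted p = 0.0678 with an estimated correlation. The integrated stress response had 8 of 32 up and 1 down, 10 and 1 adjusted over the list alone (adjusted p = 0.00396), and adjusted p = 0.206 with an estimated correlation. DDIT4, an inhibitor of mTOR signalling, rose by 0.60 ± 0.05 and the cystine transporter gene SLC7A11 fell by 0.78 ± 0.09. P53 targets had 4 of 33 up and 1 down by both counts (adjusted p = 0.00438), adjusted p = 0.187 with an estimated correlation, and with median scaling a median below 0 and adjusted p = 0.0581. DNA methylation enzymes had 0 of 11 up and 1 down by both counts (adjusted p = 0.0367), and adjusted p = 0.0557 with an estimated correlation. Without DMSO array 3, EPZ-6438 array 1 or EPZ-6438 array 2 it was 0.081, 0.0561 or 0.0524. UHRF1, which guides maintenance of DNA methylation, fell by 0.41 ± 0.07.

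In NGP, adrenergic identity genes fell and mesenchymal identity genes rose relative to other genes. DBH, the enzyme that makes noradrenaline, had the largest fall in NGP (-1.29 ± 0.09, adjusted p = 1.17e-08). Adrenergic identity genes had 0 of 27 up and 7 down, 1 and 12 adjusted over the list alone (median -0.22, adjusted p = 6.95e-05), with the LIM homeobox factor ISL1 among those that fell (-0.52 ± 0.09). Mesenchymal identity genes had 12 of 33 up and 1 down, 13 and 1 adjusted over the list alone (median 0.22, adjusted p = 2.47e-09). The homeobox factor PRRX1 rose by 1.76 ± 0.18, the collagen gene COL1A1 by 1.40 ± 0.08 and the intermediate filament gene VIM by 1.08 ± 0.07, and SOX9 was at least 2.83-fold higher. The largest rises included CDC42EP1, an effector of Cdc42 (at least 10.7-fold), the receptor gene TNFRSF14 (at least 9.11-fold), SLC35F2 (at least 4.195-fold), CYP3A7 (at least 1.93-fold), FAM43B (2.35 ± 0.30, measured on 1 of 3 DMSO arrays) and ISG15, a ubiquitin-like interferon product (2.84 ± 0.10). Of the 8 largest rises 1, and of the 8 largest falls 6, lost their call without 1 array and are not named. SNORD114-6, a small nucleolar RNA, fell by 1.09 ± 0.21, measured on 2 of 3 EPZ-6438 arrays.

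Wnt signalling rose in NGP with 8 of 25 up and 0 down, 9 and 1 adjusted over the list alone (median 0.31, adjusted p = 6.69e-07), including WNT11 (at least 2.83-fold), WNT6 (1.27 ± 0.14) and the receptor gene FZD7 (1.15 ± 0.08). BMP and TGF-beta signalling had 6 of 25 up and 1 down, 12 and 1 adjusted over the list alone (adjusted p = 4.38e-05), with the ligand gene TGFB1 up by 0.84 ± 0.10. Developmental transcription factors had 14 of 73 up and 1 down, 15 and 1 adjusted over the list alone (adjusted p = 8.49e-05), with FOXC1 and LHX1 up by 1.53 ± 0.14 and 0.96 ± 0.11. Immediate early genes had 6 of 21 up and 1 down, 8 and 1 adjusted over the list alone (adjusted p = 0.000775), with IER3 up by 0.90 ± 0.10 and MYC at least 1.48-fold higher. Genes reported as EZH2-repressed had 4 of 15 up and 1 down by both counts, the second adjusted over the list alone (median 0.17, adjusted p = 0.00102), with CDKN1C up by 1.36 ± 0.14 and the endothelial factor gene KLF2 by 1.05 ± 0.13, measured on 2 of 3 DMSO arrays. Interferon response had 4 of 18 up and 1 down, 4 and 2 adjusted over the list alone (adjusted p = 0.00194), with IFITM3 and BST2, which block virus entry and release, up by 1.19 ± 0.14 and 0.98 ± 0.12. Channels had 7 of 33 up and 2 down by both counts (adjusted p = 0.006), with the calcium channel genes CACNA1G and CACNA1H up by 1.97 ± 0.27 and 2.22 ± 0.31. HOX genes had 4 of 22 up and 1 down, 5 and 1 adjusted over the list alone (adjusted p = 0.0212), with HOXD10 up by 1.17 ± 0.08 and HOXB13 at least 2.02-fold higher. The HOX call ended with the replicate block (0.0724), without DMSO array 1 (0.0686) without slide 1 (0.1) and with other filters on dim probes (0.115 and 0.198).

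DNA replication and G1/S genes fell less widely in NGP, with 0 of 44 up and 5 down, 0 and 10 adjusted over the list alone (median -0.13, adjusted p = 1.6e-06). Set against genes of the same brightness, their median in NGP was -0.08. Mitosis genes had 0 of 44 up and 0 down by both counts (median -0.04, adjusted p = 0.763). The remaining list calls in NGP did not hold with an estimated correlation. The integrated stress response had 0 of 32 up and 6 down, 2 and 10 adjusted over the list alone (adjusted p = 0.00194), and adjusted p = 0.202 with an estimated correlation, with SLC7A11 down (-0.49 ± 0.09). P53 targets had 6 of 30 up and 1 down, 7 and 1 adjusted over the list alone (adjusted p = 0.00765), and adjusted p = 0.267 with an estimated correlation, with the apoptosis gene BBC3 up by 0.76 ± 0.08. MYC targets had 0 of 44 up and 2 down by both counts (adjusted p = 7.48e-05), and adjusted p = 0.261 with an estimated correlation. Ribosomal protein genes had 0 of 57 up and 0 down by both counts (adjusted p = 0.00499), and adjusted p = 0.653 with an estimated correlation. Without DMSO array 3 or EPZ-6438 array 1 the ribosomal adjusted p was 0.174 or 0.424, and the call also ended with median scaling (0.0887), quantile normalization (0.129) and normexp (0.157).

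In IMR32, HLA genes rose from low or unmeasured levels and hypoxia and glycolysis genes fell. HLA-B and HLA-C, of MHC class I, rose by 4.31 ± 0.18 and 4.14 ± 0.26 (adjusted p = 6.49e-12 and 1.46e-09). The class II genes HLA-DPB1 and HLA-DMB were at least 9.68-fold and 5.30-fold higher, and 3 further HLA-DPB1 probes rose by 2.45 to 4.23. CADM3, a neuronal adhesion molecule, was at least 19.2-fold, BEX5 at least 6.83-fold and SLC18B1, a vesicular polyamine transporter, at least 5.59-fold higher. Falls included ZFP36L1, which promotes decay of messenger RNA (-1.12 ± 0.10), and ZCCHC24 (-1.05 ± 0.11). Of the 8 largest falls, 2 lost their call without 1 array and are not named. Antigen presentation had 7 of 25 up and 0 down, 8 and 1 adjusted over the list alone (median 0.12, adjusted p = 1.38e-06), with a median below 0 under median scaling. Blood and endothelial cell markers had 0 of 8 up and 0 down by both counts in IMR32 (median -0.09, adjusted p = 0.904).

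Hypoxia and glycolysis genes had 3 of 25 up and 12 down, 3 and 14 adjusted over the list alone (median -0.23, adjusted p = 1.38e-06). The collagen hydroxylase gene P4HA1 fell by 0.98 ± 0.06, BNIP3, a mitophagy receptor, by 0.78 ± 0.08 and VEGFA, a growth factor of blood vessels, by 0.64 ± 0.11. Neuronal maturation genes had 7 of 40 up and 0 down by both counts, the second adjusted over the list alone (median 0.19, adjusted p = 1.07e-05), with the filament genes NEFH and PRPH up by 1.16 ± 0.09 and 0.88 ± 0.08. Channels had 7 of 34 up and 1 down, 9 and 2 adjusted over the list alone (adjusted p = 0.000143), with KCNT1 up by 1.37 ± 0.10 and KCNK10 at least 2.03-fold higher. BMP and TGF-beta signalling had 6 of 26 up and 1 down, 8 and 1 adjusted over the list alone (adjusted p = 0.000303), with the inhibin gene INHBB up by 2.33 ± 0.39. HOX genes had 4 of 16 up and 0 down, 5 and 0 adjusted over the list alone (adjusted p = 0.0179, and 0.0982 without slide 1), with HOXC13 up by 1.47 ± 0.27. Developmental transcription factors had 16 of 74 up and 3 down, 19 and 3 adjusted over the list alone (adjusted p = 0.000337), with a median below 0 under median scaling. FOXL2, a factor of the ovary, and POU3F2, a neural factor, rose by 1.80 ± 0.13 and 1.63 ± 0.17. Immediate early genes had 8 of 24 up and 0 down, 10 and 0 adjusted over the list alone (adjusted p = 4.45e-05, and 0.0885 with normexp), including EGR1 up by 1.30 ± 0.10, with a median below 0 under median scaling. Wnt signalling had 6 of 26 up and 1 down, 10 and 2 adjusted over the list alone (adjusted p = 0.00299, and 0.0524 with the filter on all 6 arrays), with a median below 0 under median scaling. LEF1, a Wnt effector, was at least 2.37-fold higher and the Wnt target SP5 rose by 1.78 ± 0.31. Notch signalling had 5 of 23 up and 0 down, 6 and 0 adjusted over the list alone (adjusted p = 0.00223), including the ligand gene DLL1 up by 1.94 ± 0.33, with a median below 0 under median scaling.

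Other list calls in IMR32 did not hold with an estimated correlation. Ribosomal protein genes had 0 of 57 up and 4 down, 0 and 2 adjusted over the list alone (median -0.17, adjusted p = 1.98e-07), and adjusted p = 0.388 with an estimated correlation. MYC targets had 0 of 44 up and 3 down by both counts (adjusted p = 9.57e-05), and adjusted p = 0.333 with an estimated correlation. The glycolytic enzyme gene LDHA, a MYC target, fell by 0.50 ± 0.09. Imprinted genes had 3 of 20 up and 1 down, 4 and 1 adjusted over the list alone (adjusted p = 0.0292), and adjusted p = 0.0934 with an estimated correlation, 0.0578 with the replicate block, 0.0816 without DMSO array 1 and 0.063 without EPZ-6438 array 3. GRB10 rose by 2.44 ± 0.17 with 2 of 3 DMSO arrays measuring it. DNA replication and G1/S genes had 0 of 44 up and 0 down by both counts (median -0.08, adjusted p = 0.0405), and adjusted p = 0.407 with an estimated correlation. Without DMSO array 1, EPZ-6438 array 2 or EPZ-6438 array 3 it was 0.16, 0.0752 or 0.119, and set against genes of the same brightness their median was 0.002. Adjusted p for replication genes was 0.692 with quantile normalization, 0.737 with normexp and 0.0617 with the filter on all 6 arrays. Mitosis genes had 0 of 44 up and 1 down, 0 and 0 adjusted over the list alone (adjusted p = 0.282). Over the lines, 60 list calls were made, of which the 46 not given here with an estimated correlation held with it. Each of the 60 lists had a median of the same sign on each of the 3 slides as over all arrays. This does not test the calls, since the lists were picked by their calls on the same arrays and each slide held every group.

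**Figure D2:**
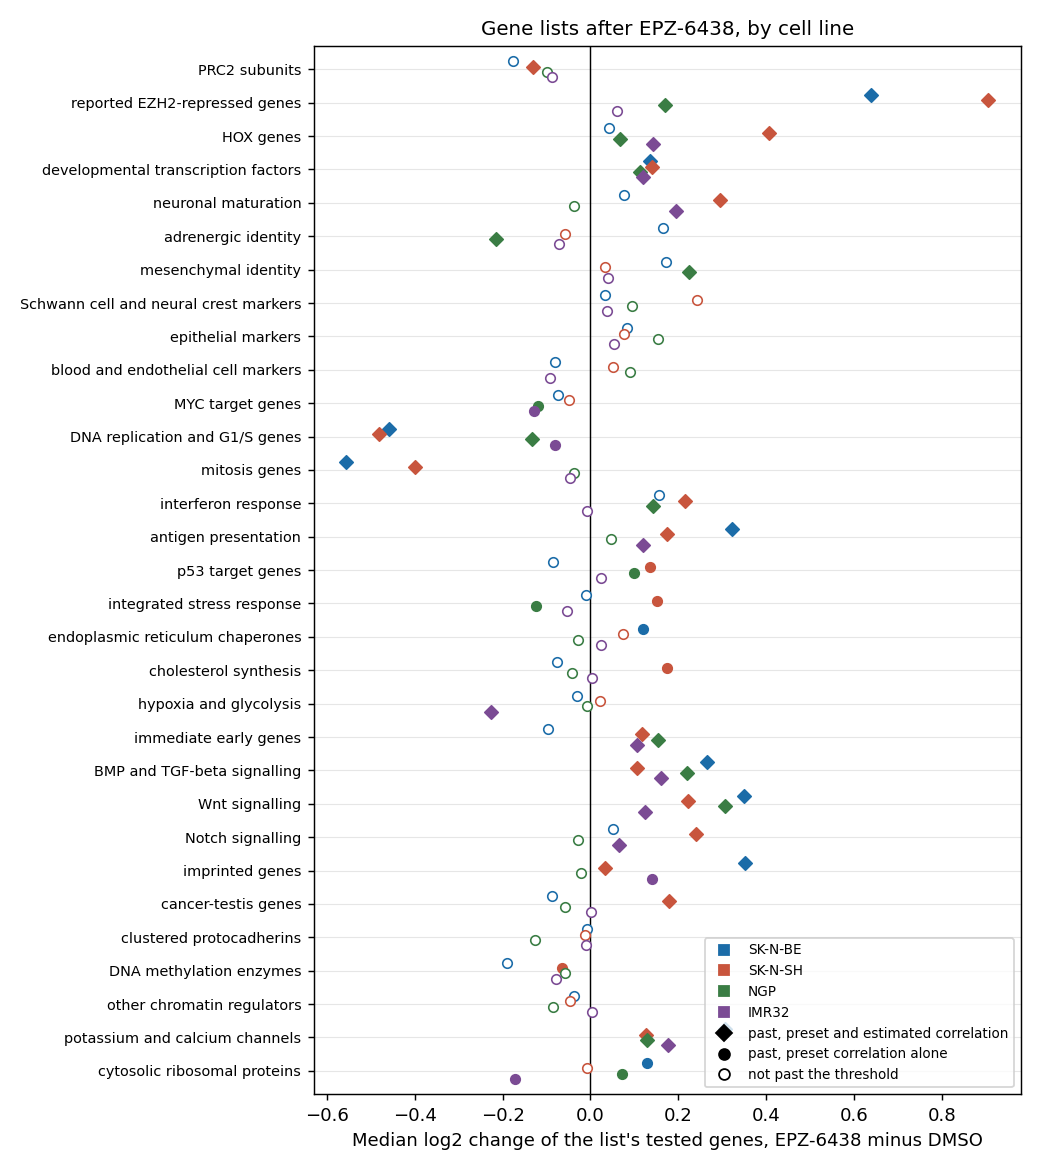
Median log2 change (EPZ-6438 minus DMSO) of each gene list in each line, with diamonds for lists past the threshold with both correlations, filled circles for the preset correlation alone and open circles for lists not past it. DNA replication genes lie at -0.46 in SK-N-BE and -0.48 in SK-N-SH against -0.13 in NGP and -0.08 in IMR32; with median scaling the medians of 14 of the 60 lists past the threshold take the other sign.

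The response averaged over the lines was given by the mean of the 4 changes, which does not show that the lines share a change, and sharing was asked through the genes called in every line and the overlap of calls. Over the lines 1681 genes rose and 2215 fell on average of 12412 tested, 57 of the rises and 0 of the falls being at least 2-fold. With median scaling the split was 701 up and 5193 down. The replicate block gave 5456 called genes on the mean, against 3896 without it. Genes called higher in all 4 lines numbered 66 and genes called lower in all of them 8. The zinc finger factor gene PLAG1 rose by 1.79 ± 0.07, HID1, which acts in formation of secretory granules, by 1.74 ± 0.06, TMEM74B by 1.64 ± 0.08 and ARHGAP44, a regulator of small GTPases, by 1.43 ± 0.05. The synaptic zinc transporter gene SLC30A3 rose by 1.38 ± 0.05, the sodium-calcium exchanger gene SLC8A2 by 1.30 ± 0.06, BEX2 by 1.28 ± 0.04 (adjusted p = 9.67e-14) and CRABP2, a carrier of retinoic acid, by 1.18 ± 0.05. PLAG1 was measured on 2 of 3 DMSO arrays in SK-N-SH, HID1 on 1 of 3 in IMR32 and TMEM74B on 1 of 3 in SK-N-BE. The neuropeptide gene TAC3 was not measurable under DMSO in SK-N-SH, where it was at least 4.62-fold higher. Of the genes lower in all lines, SAP30, a subunit of the Sin3 deacetylase complex, fell by 0.34 ± 0.02 and the repair ubiquitin ligase gene RAD18 by 0.29 ± 0.02. ISL1-DT fell by 0.47 ± 0.04, CHN1 by 0.27 ± 0.04, GABPB1, a transcription factor subunit, by 0.26 ± 0.03, KIAA0586 and POC1B, both of centrioles, by 0.26 ± 0.03 and 0.25 ± 0.03. DLEU2L fell by 0.29 ± 0.03 on its brightest probe, a call that ended with the mean of its probes (0.33).

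On the mean of the lines 17 of 29 lists were called, 14 of them with an estimated correlation too. Wnt signalling had 9 of 15 up and 0 down, 10 and 0 adjusted over the list alone (adjusted p = 1.19e-07). Neuronal maturation had 12 of 24 up and 0 down, 14 and 0 adjusted over the list alone (adjusted p = 2.72e-06). Mesenchymal identity was called on the mean too (camera, adjusted p from 2.8e-06 to 0.0334 over 39 settings), so its call was not confined to NGP. DNA replication genes had 0 of 44 up and 42 down by both counts (median -0.30, adjusted p = 1.54e-23), although in IMR32 alone 0 of 44 were called. MYC targets had 0 of 44 up and 16 down, 0 and 19 adjusted over the list alone (adjusted p = 0.000201), and adjusted p = 0.282 with an estimated correlation. Notch signalling (adjusted p = 0.0393) and imprinted genes (adjusted p = 0.00955) had adjusted p = 0.0553 and adjusted p = 0.0674 with an estimated correlation, medians below 0 with median scaling, and for Notch 0.0646 with the replicate block. With that block p53 targets and endoplasmic reticulum chaperones were also called on the mean, at 0.0414 and 0.0136.

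Each pair of lines shared more called genes than expected (one-sided Fisher's exact test, highest adjusted p = 1.37e-07 over 18 tests). Shared rises numbered 417 in SK-N-BE and SK-N-SH where 112.8 were expected, and 276 in NGP and IMR32 where 46.24 were expected. Shared falls numbered 500 in SK-N-BE and SK-N-SH, 4.67 times the expected number, and 64 in SK-N-SH and IMR32, 1.96 times. The ratios for rises of at least 2-fold ran from 9.09 to 17.2. The changes of a pair of lines correlated across genes with r from 0.28 to 0.381, and genes are not independent replicates. All lines also shared a single estimate of each gene's spread, so a gene with a small spread is more easily called in every line. Some of the excess over the expected numbers can come from this, and how much was not tested. Genes called the same way in more than 1 line numbered 1770 (1041 up), against 2973 with the replicate block and 1157 with median scaling.

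**Figure D3:**
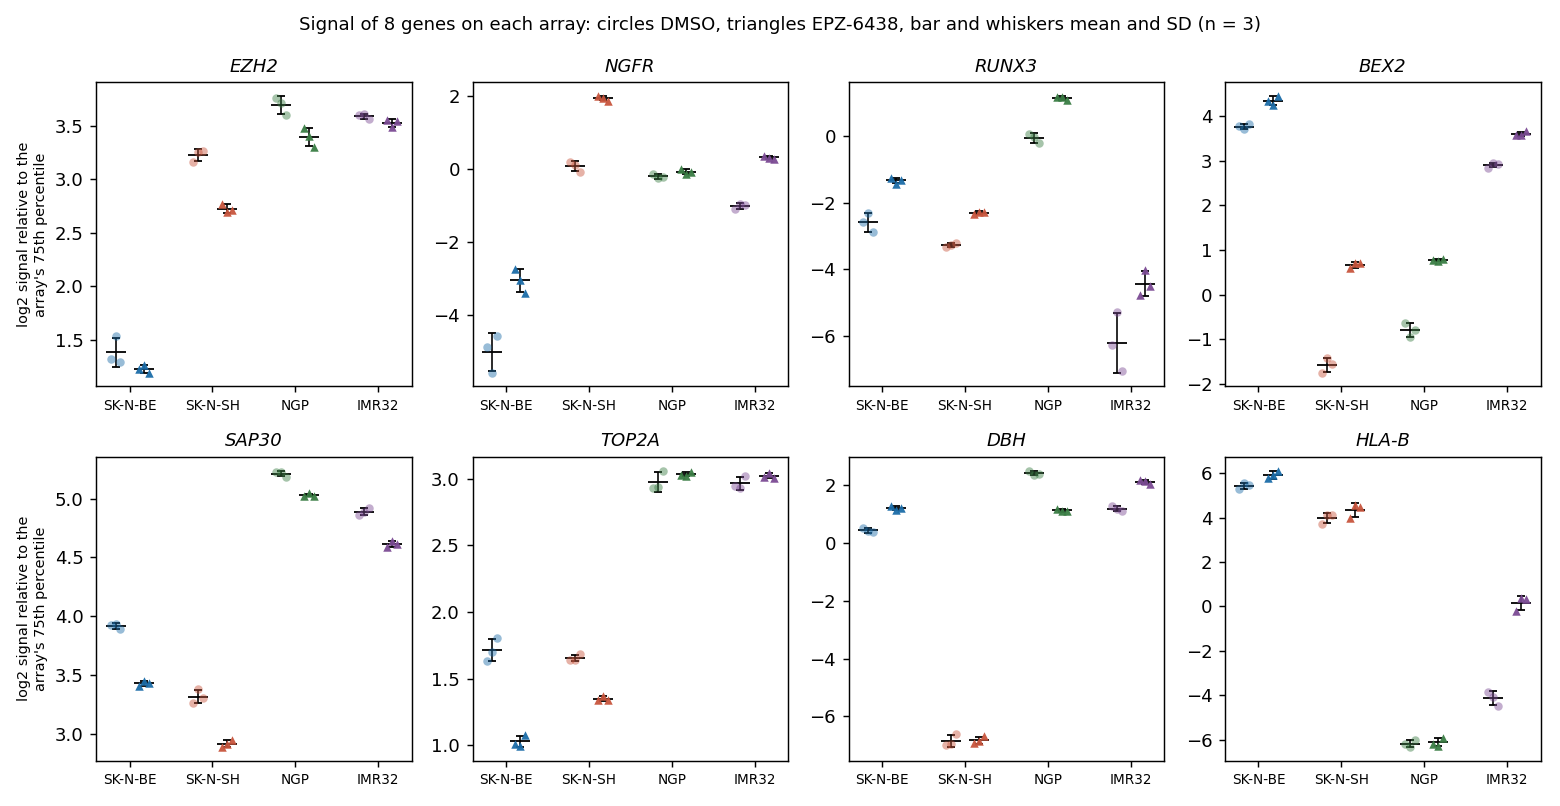
Log2 signal relative to the array's 75th percentile for EZH2, NGFR, RUNX3, BEX2, SAP30, TOP2A, DBH and HLA-B on each array, with circles for DMSO, triangles for EPZ-6438 and bars for mean ± SD (n = 3). BEX2 is higher after EPZ-6438 by 0.58, 2.24, 1.57 and 0.70 in SK-N-BE, SK-N-SH, NGP and IMR32, whereas DBH differs by -1.29 in NGP and by 0.77 and 0.93 in SK-N-BE and IMR32.

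The last question was whether the lines responded differently, which the title's theme of resistance raises. ARHGDIB rose by 4.82 ± 0.09 in SK-N-SH and fell in SK-N-BE (-0.80 ± 0.09) and IMR32 (-0.998 ± 0.085), a difference between lines at adjusted p = 5.23e-16. COTL1, an actin-binding protein, rose by 3.30 ± 0.06 in IMR32 and gave 0.00, 0.06 and 0.14 in SK-N-BE, SK-N-SH and NGP (adjusted p = 5.52e-15). CD24 was at least 53.8-fold higher in SK-N-SH, rose by 2.08 ± 0.14 in SK-N-BE and gave -0.08 and -0.06 in NGP and IMR32. EMILIN2, an extracellular matrix protein, rose by 3.21 ± 0.08 in SK-N-SH and fell in IMR32 (-0.48 ± 0.08). The chemokine CCL2 was at least 4.31-fold higher in IMR32 and rose by 0.63 ± 0.08 and 0.79 ± 0.08 in SK-N-BE and SK-N-SH. IGF2BP1, which binds messenger RNA, rose by 3.45 ± 0.08 in SK-N-SH, measured on 2 of 3 DMSO arrays, and gave -0.02 and -0.22 in NGP and IMR32. NELL2, a secreted neuronal protein, was at least 3.67-fold higher in SK-N-SH, rose by 0.45 ± 0.06 in SK-N-BE and fell in IMR32 (-0.30 ± 0.06). SELENOP was measured in SK-N-BE alone. DBH rose in SK-N-BE and IMR32 and fell in NGP (difference between lines, adjusted p = 8.68e-10).

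Of 16487 genes tested, 3710 differed in response between the lines, 1376 of them with lines at least 2-fold apart, and 338 genes rose in a line and fell in another. IMR32 was taken on day 4 and the others on day 3, so its line and day cannot be separated. Genes that differed between pairs numbered 1834 (SK-N-BE and SK-N-SH), 2122 (SK-N-BE and NGP), 2307 (SK-N-BE and IMR32), 1491 (SK-N-SH and NGP), 1567 (SK-N-SH and IMR32) and 1007 (NGP and IMR32). Over all pairs 4476 genes differed, against 6730 with the replicate block and 2195 with median scaling. Among the genes named in any case, the response differed for NGFR (adjusted p = 6.67e-05), CASZ1 (8.1e-05), EZH2 (0.0059), MYCN (0.0075) and CLU (0.0218), and no difference was called for SUZ12 (0.688) and EZH1 (0.493). RUNX3 had adjusted p = 0.46 for the difference, and it was called with normexp (3.87e-07), without IMR32 DMSO array 2 (0.0124) and without the 3 arrays marked for evaluation (0.0239). The EZH2, MYCN and CLU differences ended with median scaling (adjusted p = 0.247, 0.259 and 0.421), and those of EZH2 and MYCN without slide 1 (0.0611 and 0.143). The CLU difference also ended without IMR32 DMSO array 2 (0.0567), DMSO array 3 (0.062) or EPZ-6438 array 1 (0.0675), with quantile normalization (0.0706) and with normexp (0.218).

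Replication and mitosis genes separated SK-N-BE and SK-N-SH from NGP and IMR32. Relative to SK-N-BE, the replication response was higher for 23 of 44 genes in NGP (median difference 0.32, adjusted p = 4.03e-13) and 30 in IMR32 (0.39, adjusted p = 4.99e-18). Relative to SK-N-SH it was higher for 24 in NGP (0.38, adjusted p = 7.28e-19) and 28 in IMR32 (0.41, adjusted p = 7.05e-25). The mitosis response was higher by a median of 0.51 and 0.53 in NGP and IMR32 than in SK-N-BE (adjusted p = 5.31e-28 and 1.84e-25), and by 0.37 and 0.36 than in SK-N-SH (adjusted p = 7.13e-23 and 2.09e-21). These calls held with an estimated correlation, as did those on the lists that follow apart from adrenergic genes. The hypoxia response was lower in IMR32 than in SK-N-BE, SK-N-SH and NGP (adjusted p = 8.14e-05, 6.56e-06 and 8.78e-05). The neuronal maturation response was higher in SK-N-SH than in SK-N-BE (median difference 0.27, adjusted p = 0.000283) and NGP (adjusted p = 6.15e-06), and higher in IMR32 than in NGP (adjusted p = 0.000134). The response of HOX genes was lower in NGP and IMR32 than in SK-N-SH (adjusted p = 0.00315 and 0.0115), and that of genes reported as EZH2-repressed was lower in NGP than in SK-N-SH (adjusted p = 0.000992). That of imprinted genes was lower in NGP than in SK-N-BE (adjusted p = 0.000882), and that of antigen presentation was higher in IMR32 than in NGP (adjusted p = 0.00439). Adrenergic genes had medians of opposite sign in NGP, where the list fell, and SK-N-BE, where it was not called (adjusted p = 0.000241 for the difference, and adjusted p = 0.0525 with an estimated correlation).

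A further question was how the lines differed under DMSO, before any response. MYCN signal relative to the 75th percentile was 7.07 ± 0.12 (SD, log2, n = 3) in SK-N-BE, 7.24 ± 0.08 in NGP and 6.46 ± 0.07 in IMR32, and it was not above background in SK-N-SH. EZH2 was lower in SK-N-BE (1.38 ± 0.13) than in SK-N-SH (3.23 ± 0.05), NGP (3.69 ± 0.09) and IMR32 (3.59 ± 0.02), a difference between lines at adjusted p = 6.12e-17 (limma). COL1A1 stood at 5.47 in SK-N-SH against -2.34, -0.14 and -0.71 in SK-N-BE, NGP and IMR32 (adjusted p = 1.04e-22). HLA-B stood at 5.43 in SK-N-BE, 3.98 in SK-N-SH and -4.14 in IMR32, and was not above background in NGP. Of 16487 genes, 15464 differed between the lines under DMSO, 11449 of them with lines at least 2-fold apart.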

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

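The tests on the HLA genes of IMR32 were chosen only after the result was seen. Rises of at least 2-fold outnumbered falls in every line, with 390 against 6 in SK-N-BE and 320 against 9 in IMR32. Array scaling as the whole cause was argued against, since rises made up at least 92.1% of such changes in every line under the other scalings. A signal floor that hides falls was argued against too, for changes of at least 2-fold. Among genes at least 3 log2 units above the floor, such rises numbered 102, 79, 55 and 87 in SK-N-BE, SK-N-SH, NGP and IMR32. Such falls numbered 0, 0, 1 and 2, and the lowest end of the exact 95% intervals was 90.4%. At any size those genes had 1275 rises and 1497 falls in SK-N-BE and 638 and 809 in SK-N-SH. The counts were 471 and 368 in NGP and 536 and 459 in IMR32. The excess of rises of any size in SK-N-BE and SK-N-SH was thus absent among genes that far above the floor. No biological explanation of the imbalance was tested, and no array measured the repressive mark.

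DNA replication and mitosis genes fell in SK-N-BE and SK-N-SH. A difference between arrays that depends on brightness was argued against, since the medians of both lists lay below those of genes of the same brightness by a log2 difference of -0.382 or further from 0. A difference between slides was not tested by the values within slides, since each slide held every group and such a difference cancels in the comparison, and those medians were -0.381 or further from 0 in both lines. This holds for these lines alone, since against genes of the same brightness the replication genes had a median of -0.08 in NGP and 0.002 in IMR32, where their medians were -0.134 and -0.08, so brightness stays open as a source of much of the shift there. No biological explanation was tested, growth was not measured, and the difference from IMR32 cannot be separated from its later day.

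HLA genes rose in IMR32. Blood cells in the culture were argued against, since the blood and endothelial markers had a median of -0.093 with a spread of 0.182, 0 of 8 were called higher and the highest was PTPRC at 0.385. Sequence shared by HLA class I genes was argued against for HLA-E, HLA-F and HLA-G, whose highest change was 0.967 where HLA-B rose by 4.31. HLA-B and HLA-C cannot be told apart in this way, because their probes can share targets. No biological explanation of the HLA rise was tested.

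A difference between lines in the response drew attention to further results. The response differed between the lines for 3710 genes. It differed between SK-N-BE and SK-N-SH for 1834 genes and 7 lists, between SK-N-BE and NGP for 2122 genes and 4 lists, and between SK-N-BE and IMR32 for 2307 genes and 6 lists. Between SK-N-SH and NGP it differed for 1491 genes and 13 lists, between SK-N-SH and IMR32 for 1567 genes and 11 lists, and between NGP and IMR32 for 1007 genes and 6 lists. Of these list differences 1, 3, 3, 5, 4 and 3 held with an estimated correlation. The fitted log2 response of the highest line exceeded that of the lowest by 5.82 for ARHGDIB, 3.30 for COTL1, 6.77 for CD24, 3.68 for EMILIN2, 3.78 for CCL2, 4.76 for SELENOP, 3.67 for IGF2BP1 and 2.54 for NELL2. Those of CD24, CCL2, SELENOP and NELL2 rest on a group that was not above background and are no bounds. Among the genes named in any case the range was 0.44 for EZH2, 1.23 for CASZ1, 0.52 for CLU, 1.82 for NGFR and 0.48 for MYCN, where the NGFR value includes a group not above background.

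Probes that match no RefSeq symbol stood outside the comparisons by gene and also gave calls. Of 6255 such probes tested in SK-N-BE 285 changed (159 up, 126 down), and of 6158 in SK-N-SH 173 changed (123 up, 50 down). Of 5444 in NGP 107 changed (60 up, 47 down), and of 5858 in IMR32 96 changed (77 up, 19 down).

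Other groupings of the same arrays were compared with the treatment. Each line's 6 arrays allow 10 splits, too few for a share under 0.05, and 1 of them, the treatment itself, gave as many genes as observed. The treatment gave 3524, 2062, 1328 and 1451 genes in SK-N-BE, SK-N-SH, NGP and IMR32, and the highest other split gave 1, 2, 2 and 2. The 3 other splits that part all pairs gave at most 1, 0, 2 and 1. For the mean of the lines 1 of 100 splits, the treatment itself, gave as many genes (3896, highest other 2186). Splits that mix treated and control arrays carry the treatment difference in their spread, so their counts are no chance level. Regrouping these arrays cannot exclude a chance difference between cultures, since the labels do not say that replicates were separate cultures. For the difference between lines 1 of 100 gave as many genes (3710, highest other 2514). Those splits cannot decide whether the lines differ, since regrouping within a line also removes a response that the lines share. The highest others for the mean and the difference kept the treatment split in 3 and 2 of the lines. Among the 62 splits that kept it in no line the highest were 0 and 7.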

How the results depend on the processing

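The settings without slide 1 and without the 3 arrays marked for evaluation were chosen after the data were seen. No list or named gene was reversed in any setting, where the direction of a list is that relative to the other genes. Counts could not be marked as reversed. With median scaling, which rests on spots near background, falls outnumbered rises in SK-N-BE and SK-N-SH. The medians of 14 of the 60 lists past the threshold then took the other sign. With quantile normalization, alone or after normexp, 0 of the 60 medians did. In every setting 115 of 153 list results and 220 of 504 results on named genes kept their side of the threshold. The settings include stricter thresholds, which end calls by construction. Asking for at least 2-fold ended 219 of the 504 gene results, and an adjusted p under 0.01 ended 77. With the median of each array as the scaling, the counts were 541 in NGP, 833 in IMR32, 5894 on the mean of the lines, 1846 for the difference between lines, 2195 over all pairs and 1157 for genes called in more than 1 line. With the replicate block 2268 genes were called in NGP, 2641 in IMR32, 6730 over all pairs and 2973 in more than 1 line. With the slide block these were 2439, 2704, 6874 and 3065, and 5731 genes differed between lines. Each line fitted alone gave 858 genes in NGP. The cause of these shifts was not tested. A stricter threshold leaves fewer genes by construction. At an adjusted p under 0.01 there were 2275, 1344, 754 and 833 genes in SK-N-BE, SK-N-SH, NGP and IMR32, 2560 on the mean, 2335 for the difference between lines, 2699 over all pairs and 1067 in more than 1 line. At a change of at least 2-fold these counts were 396, 425, 211, 329, 57, 1376, 1454 and 195. Leaving out 1 array at a time gave 2846 to 3213, 1644 to 1747, 972 to 1098 and 1053 to 1208 genes in the lines, 3545 to 3908 on the mean, 3405 to 3660 for the difference between lines, 4102 to 4439 over all pairs, 1601 to 1702 in more than 1 line and 58 to 61 list calls. Without slide 1 the line counts were 3004, 1557, 948 and 988, and without the 3 marked arrays 3173, 2053, 1025 and 1080. List calls ranged from 46 with an estimated correlation to 67 with no filter on dim probes. Over the settings, adjusted p for EZH2 in NGP ran from 0.00192 to 0.0885, for SUZ12 in IMR32 from 0.00423 to 0.247, for CLU in IMR32 from 1.15e-06 to 0.147, for RUNX3 in SK-N-SH from 0.000226 to 0.233 and for MYCN in SK-N-BE from 0.00608 to 0.525. The replicate block also called MYC targets in SK-N-BE and SK-N-SH (0.0251 and 0.038). Among list differences between pairs it ended immediate early genes in SK-N-BE and IMR32 (0.0652), Notch signalling and imprinted genes in SK-N-SH and NGP (0.0671 and 0.0728) and antigen presentation in SK-N-SH and IMR32 (0.257). It gained antigen presentation and endoplasmic reticulum chaperones in SK-N-BE and NGP (0.0405 and 0.0245) and DNA replication genes in NGP and IMR32 (0.0209). Beyond these and those given with the results above, the replicate block changed no call on a list or gene given there. The difference between lines under DMSO could not be fitted with the block within lines, the list count is not defined at 2-fold, and the block by scan date was not run. Genes near background limit the rest, since 49.6% to 55.2% of spots were well above it.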

Other observations

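The test of risen genes well above background under DMSO was chosen only after the result was seen. Markers of other cell types and further gene groups gave no list call in any line. Markers of Schwann cells, the glia of peripheral nerves, had medians of 0.03, 0.24, 0.09 and 0.04 in SK-N-BE, SK-N-SH, NGP and IMR32 (adjusted p = 0.649, 0.213, 0.298 and 0.831). PMP22, a myelin protein among them, rose by 0.64 in NGP. Epithelial markers had medians of 0.08, 0.08, 0.15 and 0.05 (adjusted p = 0.477, 0.212, 0.354 and 0.282), and CLDN3, a tight junction claudin among them, rose by 1.76 in SK-N-BE. Blood and endothelial markers had medians of -0.08, 0.05, 0.09 and -0.09 (adjusted p = 0.592, 0.199, 0.906 and 0.904), and CD3D, a chain of the T cell receptor complex, rose by 1.96 in SK-N-SH. This list was called in SK-N-SH with median scaling (adjusted p = 0.0286), with normexp (0.0437) and without EPZ-6438 array 1 (0.045), where the alternatives ran from 0.0286 to 0.57. Clustered protocadherins, adhesion molecules of neurons, had medians of -0.01, -0.01, -0.13 and -0.01 (adjusted p = 0.946, 0.767, 0.202 and 0.96), with a call in NGP under normexp (0.0411). Other chromatin regulators had medians of -0.04, -0.05, -0.09 and 0.00 (adjusted p = 0.732, 0.215, 0.346 and 0.904), although SMARCA2, an ATPase of SWI/SNF remodellers, rose by 1.60 in IMR32. The median, mean and test of a list differed in sign for 5, 1, 5 and 6 lists in the lines, for 2 on the mean of the lines and for 4, 3, 8, 6, 3 and 6 in the pairs, and 0 of these lists were called.

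Some genes changed in lists that were not called. LMO1, an adrenergic regulator reported as a neuroblastoma oncogene, rose by 1.62 in SK-N-SH and 1.056 in IMR32, where the adrenergic list had adjusted p = 0.215 and 0.463. PDGFRA, a growth factor receptor of mesenchymal cells, rose by 1.12 in SK-N-SH and 1.69 in IMR32, where the mesenchymal list had adjusted p = 0.276 and 0.227. In SK-N-BE the mesenchymal list had adjusted p = 0.052, was called in 7 of 21 other settings (range 0.0224 to 0.333) and had medians of 0.111, 0.122 and 0.159 on the slides. ADM, a vasodilator peptide of the hypoxia list, rose by 1.60 in SK-N-BE, where P4HA1 fell by 0.53 and the list had adjusted p = 0.416. FOS and NR4A3, immediate early factors, rose by 1.20 and 1.56 in SK-N-BE and SPRY2, an inhibitor of growth factor signalling, fell by 0.64 there, with adjusted p = 0.686 for the list.

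A hypothesis written before its first test was that the genes that rose at least 2-fold in a line were genes held low in that line compared with the others. Levels were taken from slide 1 and rises were called on the other slides. The 382, 380, 193 and 276 risen genes of SK-N-BE, SK-N-SH, NGP and IMR32 lay lower against the DMSO arrays of the other lines than unchanged genes of the same level did, by medians of -1.069, -0.639, -1.665 and -0.776 on the log2 scale. The bootstrap intervals were -1.348 to -0.752, -1.188 to -0.232, -2.112 to -1.254 and -1.112 to -0.333. Of the risen genes 63.4%, 67.9%, 72.5% and 64.9% lay below the other lines, against 45.4%, 65.3%, 48.4% and 58.6% of unchanged genes, a share whose definition was corrected after it had first been seen. Many risen genes were at background under DMSO, where unchanged genes of the same level are few. Among the 228, 173, 120 and 161 risen genes well above background on all DMSO arrays of the line, the medians were -0.672, -0.476, -1.673 and -0.193, with bootstrap intervals of -1.172 to -0.163, -1.192 to 0.131, -2.369 to -1.142 and -0.798 to 0.479. The intervals lay below 0 in SK-N-BE and NGP and included 0 in SK-N-SH and IMR32, so the hypothesis stays open for the lines as a whole.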
